A study of Mus musculus with 12 samples.

How the data were processed

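RNA of 12 mouse cell samples was measured on 2-colour Agilent oligonucleotide arrays, 6 groups with 2 arrays each. Per the labels, each sample was in the Cy3 channel and a pooled reference RNA in the Cy5 channel on every array, with no dye swap. A fixed dye effect of a probe is shared by all arrays and cancels in differences between groups. An effect that varies with the sample signal would not cancel, and some reference signals moved with the sample signal. Groups were taken from the titles and descriptions. For the second 4-day array these give the 4-day group while the source name reads as a brain control, and the array was kept in the 4-day group.

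Spot brightness (intensity) was read from the deposited scanner files, which were made with Feature Extraction A.7.1.1, per the file headers. The mean signal and the median local background of each channel, as deposited, are intensity values that had not been normalized. The files also hold a log10 ratio of Cy5 to Cy3 that the scanner software had background-subtracted and dye-normalized, per the file headers. A value table deposited for the whole series was on a log10 scale: its columns correlated at 0.981 to 0.992 with the log10 scanner signal of the sample channel and all had a median of 3.02. Its scale and direction were settled by that comparison, while its centring and normalization are not given in the sources used here.

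Each array held 22132 spots, of which 1080 were controls and 21052 were probes. Background was corrected with normexp at an offset of 50, and ratios were normalized within each array by loess with control spots and spots marked as outliers at weight 0, in limma 3.58.1 under R 4.3.3 (files were read with the data.table package, version 1.17.8). The sign was turned to sample over reference and values are log2. Of the probes, 305 that were not well above background in the sample channel on both arrays of any group were removed. A further 224 with an outlier mark on any array were removed, a choice made after first counts of changed features had been seen. For genes with several probes the probe with the highest mean sample signal was kept, which removed 266, and 20257 features were tested. Gene symbols came from RefSeq accessions matched to the GRCm38.p6 gene table, used for names only. A symbol was found for 10422 probes and none for 10630, and 9968 of the tested features had one. The genome build of the probe design is not given in the sources used here, so no coordinates are printed. Of 234 genes with several probes, 0 had opposite calls in EB4 against ES, RA1 against EB4 or RA4 against EB4. The other comparisons were not checked for this.

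Sample signals well above background made up 96.0% to 98.6% of probes per array and reference signals 94.5% to 98.1%. Between 43 and 101 sample spots per array were saturated and were kept. The number of arrays limits the precision. Arrays of the same group correlated at 0.935 to 0.975 across features.

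One linear model over all 6 groups was fitted with lmFit and eBayes (6 residual and 3.19 prior degrees of freedom), with 10 comparisons and Benjamini-Hochberg adjustment within each at a threshold of 0.05. The 22 gene lists were tested in 4 comparisons, 88 tests adjusted together, with camera at a preset correlation of 0.01, with camera at a correlation estimated from the data, and with fry. At the preset correlation 37 tests passed, 22 up and 15 down. With the estimated correlation camera passed 0, against 12 at an unadjusted p under 0.05 and 27 by fry, which does not compare a list with other genes. Lists overlap: Meis1, Meis2, Nr2f1 and Nr2f2 stand among both retinoid and neural progenitor genes, and Stra8 among both retinoid and germ cell genes.

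The groups, comparisons, gene lists and the rule for named genes were fixed before the data were examined. Named were the 12 largest rises and falls of genes with a symbol in EB4 against ES, RA1 against EB4 and RA4 against EB4, and the 4 largest each way in the other comparisons. Each had to pass the test, to have both arrays of a group beyond both of the other, and to be well above background on both arrays of the brighter group. Up to 4 largest changes per gene list were named too. Other list members, and the second probe of Tdgf1, were picked after their values were seen. Some genes that the rule takes are not reported here.

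Arrays with the same replicate number shared the date on which the scanner software processed their images, per the file headers. The arrays of each of these 2 dates are called a batch here. Each batch held all 6 groups, so that batch and replicate number are a single block. No date of culture, labelling or hybridization was used, so a batch need not be a separate experiment. Differences between the batches correlated across features at 0.248 to 0.650 (median 0.472) in all 15 pairs of groups, each above 0.1, and the numbers were taken to pair the arrays. The block was an alternative, and the comparisons were fitted without it. The batch difference thus stayed in the spread of the main fits, and each comparison called more features with the block.

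Alternatives fixed beforehand were no background correction, the scanner software's own ratio, median centring, Aquantile between arrays, the deposited value table, no filter on dim probes, all probes, the block, fits of only both groups compared, and each array left out in turn. In the latter a lone array was assumed to vary like the other groups. Added after seeing the data were the sample channel alone (quantile-normalized), the block together with an estimated correlation, the second RA4 array left out together with an estimated correlation, 1 EB4 array for each comparison in the overlap of calls, and 5 further gene lists, tested also without the genes that the rule had named. Groups of 2 arrays are too small for a test of outlying samples or of other splits of the samples.

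The overlap of calls was set against 100 simulations of unchanged groups that share the same EB4 arrays. The test was checked on simulated data for RA1 against EB4 with 200 of 21052 features changed. At 1.5-fold 37 of 67 were recovered, at 2-fold 65 of 67 and at 4-fold 66 of 66, with 12 false calls. Of 50 unchanged lists of randomly drawn features 1 fell under 0.05. The simulated noise was independent between features and held no batch difference. The check therefore does not cover lists whose members vary together, as those of the measured lists can. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.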

Results

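Gene expression was measured along a neural induction protocol in mouse embryonic stem cells of the 129/SvEv background, a pluripotent line that can be turned into many cell types in culture. The 6 groups were undifferentiated cells kept with the cytokine LIF (ES), cell aggregates called embryoid bodies after 4 days without LIF (EB4), and EB4 aggregates after 1, 2, 3 or 4 further days in 1 µM retinoic acid, a vitamin A derivative that drives neural fates (RA1 to RA4). The labels give this dose for all of these arrays except the second RA4 array, whose labels state no dose. Each group had 2 arrays, 12 in all, and each array compared 1 sample in the Cy3 channel with a pooled mouse reference RNA in the Cy5 channel. Between 96.0% and 98.6% of the 21052 probes per array were well above background in the sample channel, and the median sample brightness lay between 656 and 789. All values are log2 ratios of sample to reference, and differences between groups are given ± SE with n = 2 arrays per group. That SE is moderated and pooled over all 12 arrays, so a gene has the same SE in every comparison. The labels do not say that the 2 arrays of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical. No aggregates of the same age without retinoic acid were among the samples, so each comparison of RA1 to RA4 with EB4 holds both the treatment and the extra days of culture.

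The comparison of EB4 with ES asks what 4 days of aggregation without LIF changed. Of the pluripotency list, Nr0b1 (-2.58 ± 0.42, 6.00-fold), Spp1, which encodes osteopontin (-2.38 ± 0.53), and Klf4, a reprogramming factor (-2.11 ± 0.09, adjusted p = 7.16e-06), fell in EB4. Gsc (2.40), Pdgfra (2.06) and T (brachyury, 1.55) rose, members of the list for the primitive streak, where mesoderm and endoderm form in the embryo. The largest rise among named genes was that of Asb4, a ubiquitin ligase adaptor (3.94 ± 0.15, 15.3-fold). The lipoprotein receptor Vldlr (3.40 ± 0.33), the interferon-induced protease Usp18 (3.30 ± 0.25) and the neuronal serine protease Prss12 (3.26 ± 0.12) rose too. Cyp26a1, the enzyme that degrades retinoic acid, was already 8.67-fold higher before any retinoic acid was added (3.12 ± 0.15).

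Further rises were measured for Rgs5 (3.17), Adssl1 (2.96), the homeobox gene Msx1 (2.68), the chemokine receptor Ackr3 (2.67), the Wnt antagonists Dkk1 (2.54) and Apcdd1 (2.52), and the stress-induced Ddit4 (2.42). The largest fall among named genes was that of Cltb, a clathrin light chain (-2.79 ± 0.17), and the fatty acid transporter Slc27a2 fell by 2.30 on the log2 scale. The drug efflux pump Abcb1b (-2.07), the Hedgehog target Gli1 (-1.94), the cytokine signalling inhibitor Socs3 (-1.92), the folate receptor Folr1 (-1.91), Jam2 (-1.90), Rpl39l (-1.88) and Neurod1 (-1.84) fell as well. Of 26 pluripotency genes measured, 11 fell, 0 rose and 15 did not pass the test, or 16 falls adjusted over the list alone. Pou5f1, which encodes Oct4, was among the 11 at -1.36. Lefty1 stood at -1.70 and did not pass (adjusted p = 0.0728), but passed with the batch as a block (adjusted p = 0.00352), and the block gave 18 falls in the list. The list ranked low against all other genes by camera (adjusted p = 2.06e-08), but adjusted p = 0.337 with an estimated correlation.

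Of 20 primitive streak and mesoderm genes, 10 rose and 1, Tcf15 (-1.47), fell, and the counts were the same adjusted over the list alone (camera adjusted p = 2.73e-06, and adjusted p = 0.0840 with an estimated correlation). The hypoxia and glycolysis list had 8 of 19 members higher, or 9 adjusted over the list alone, with the oxygen-sensing hydroxylases Egln3 (1.98) and Egln1 (1.37) and the collagen hydroxylase P4ha1 (1.54) in front (camera adjusted p = 1.44e-05, and adjusted p = 0.427 with an estimated correlation). Among 25 endoderm genes 7 rose and 4 fell, or 8 and 4 adjusted over the list alone, with Foxa2 at 2.25 and Sox17 at 2.06. That list did not pass (adjusted p = 0.0572), but passed with the batch as a block (adjusted p = 0.0331, and adjusted p = 0.434 with the block and an estimated correlation). In the cell division list 6 of 22 members fell and 1 rose, or 7 and 1 adjusted over the list alone. Ccne1, a cyclin of the entry into S phase, was at -1.26 and Bub1, the riser, at 0.39 (camera adjusted p = 0.00591, and adjusted p = 0.448 with an estimated correlation). Neuronal genes ranked low with 5 of 38 lower, on either adjustment, or 9 with the batch as a block, led by Neurod1 and Gap43 (-1.59), at adjusted p = 0.0176 without the block, and adjusted p = 0.631 with an estimated correlation. Germ cell genes ranked low with 5 of 14 lower, or 6 adjusted over the list alone, among them Ddx4 (-1.07), at adjusted p = 0.0291, and adjusted p = 0.424 with an estimated correlation. Stra8 was at -0.92 in that list and turned to 1.37 on the deposited table of values. Without the second ES array the calls of P4ha1, Tcf15, Ddx4 and Stra8 ended (adjusted p = 0.102, 0.0686, 0.0593 and 0.218).

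Lists that did not pass still held single changes. The retinoid list (adjusted p = 0.0988) had 3 rises, Cyp26a1 among them, and 2 falls, of Skil (-0.97) and Stra8. The neural crest list (adjusted p = 0.225) had 3 rises, Msx2 (1.47) among them, and 1 fall, of Foxd3 (-1.48). In the heart and muscle list (adjusted p = 0.228) 3 rose, the troponin Tnnc1 (2.07) among them, and 0 fell. The primed epiblast list (adjusted p = 0.773) had a mean of -0.24. Of its 10 members Fgf5 (0.60) and Lef1 (0.35) rose and Foxd3 fell, or 2 rose and 4 fell adjusted over the list alone, and 3 and 4 with the batch as a block. The call of Fgf5 ended without the first ES array (adjusted p = 0.0949) and on the sample channel alone (adjusted p = 0.0722). The 38 neural progenitor genes split evenly, 3 higher and 3 lower, with a median of -0.04, a mean of 0.06 and a test direction that was downward (adjusted p = 0.965). Median, mean and test also differed in sign for Hox groups 1 to 5, glia, trophoblast and cell cycle inhibitors, none of which passed (adjusted p = 0.784, 0.907, 0.459 and 0.749).

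Over the array, 2865 of 20257 features changed at an adjusted p under 0.05 (limma), 1334 higher and 1531 lower, of which 482 changed at least 2-fold. Changes over all features correlated at 0.854 between the 2 batches of arrays. The count was 4577 with the batch as a block, 4770 on the deposited table, and 1861 on the sample channel alone. It was 1770 and 1604 without the first and the second ES array and 1774 without the first EB4 array. Of the 2865 features 2401 were also called on the deposited table and 1545 on the sample channel alone. Asb4 stood at 4.82 (28.3-fold), Gsc at 3.48 and Tcf15 at -2.66 on the sample channel alone, each over 1.5-fold further from 0, and Stra8 lost its call there (adjusted p = 0.481). Of 66 changes named for this comparison 24 lost their call in a fit without 1 array and 20 under at least 1 other setting. Msx1, Spp1, Pdgfra and Jam2 lost theirs without the second ES array (adjusted p = 0.0733, 0.108, 0.171 and 0.0788).

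**Figure D1:**
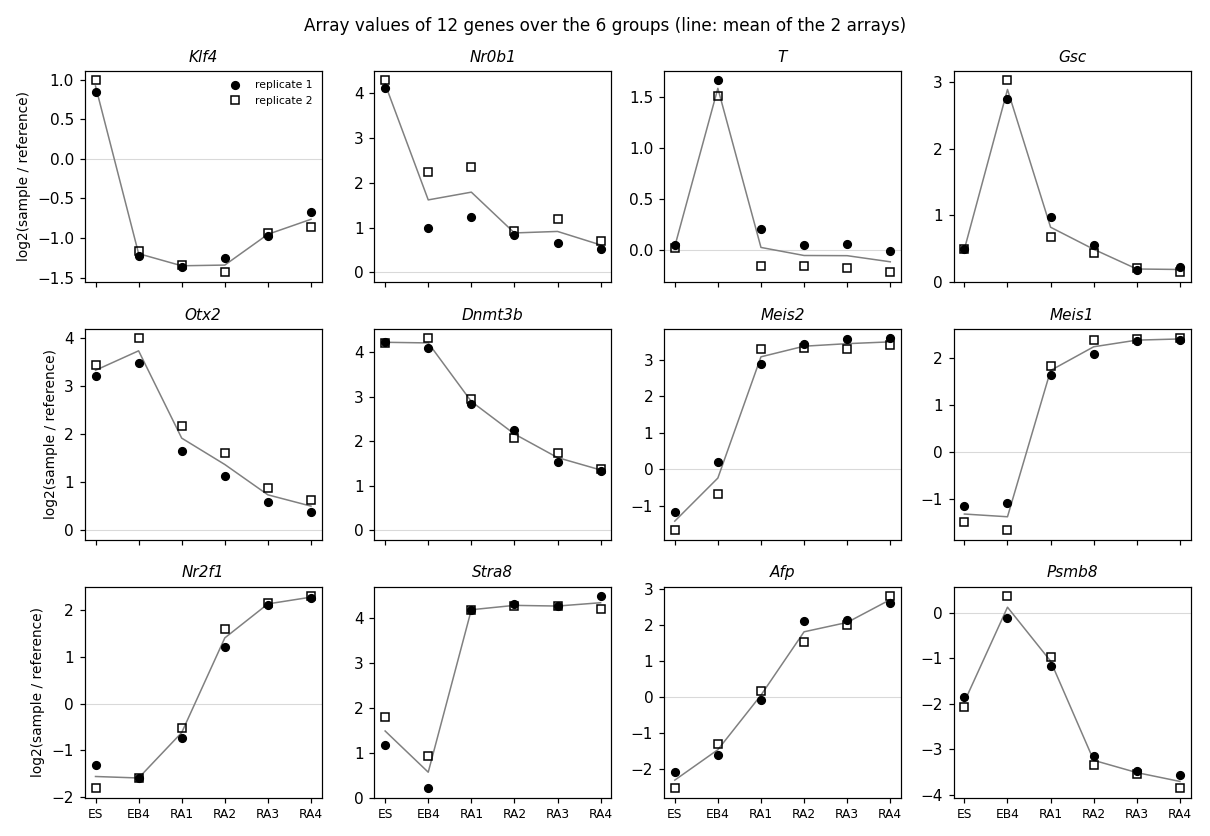
Log2 ratio of sample to reference (vertical axis) of 12 genes over the 6 groups (horizontal axis), with 1 point per array (filled circles for replicate 1, open squares for replicate 2) and a line through the group means; vertical scales differ between panels. Klf4 drops from ES to EB4, T and Gsc peak at EB4, Stra8 and Meis2 rise at RA1, and Nr2f1 and Afp climb through RA4.

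The comparison of RA1 with EB4 covers the first day in retinoic acid. Stra8, named for its induction by retinoic acid, rose 12.3-fold (3.62 ± 0.24, adjusted p = 0.000204). The homeobox cofactors Meis2 (3.32 ± 0.27) and Meis1 (3.11 ± 0.18) and the neural plate gene Irx3 (2.26 ± 0.17) rose alongside. The primitive streak genes Gsc (-2.07 ± 0.12), Wnt3 (-1.63 ± 0.20) and T (-1.56 ± 0.14) fell. The reference signal of some strongly changed genes moved in the direction of the sample signal. On the sample channel alone Stra8 stood at 6.18, Irx3 at 3.02 and Gsc at -2.94. Over all comparisons 177 of 253 named changes were larger there, with a median ratio of the log2 changes of 1.06.

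Other rises were those of Wnt2 (2.32), Zadh2 (2.05), the differentiation inhibitor Id2 (2.00), Zfp503 (1.93), tissue plasminogen activator Plat (1.89), Cdc42ep1 (1.73) and Cltrn (1.68). Other falls were those of Chst7 (-2.05), Vldlr (-1.89), the chemokine receptor Cxcr4 (-1.87), Usp18 (-1.85), the anterior epiblast gene Otx2 (-1.81), Pdlim3 (-1.60), Bmper (-1.58) and the interferon-inducible GTPase Irgm1 (-1.51). Of 23 genes of retinoid metabolism and response 6 rose and 0 fell, or 12 and 1 adjusted over the list alone, and 12 and 0 with the batch as a block (without the block camera adjusted p = 2.58e-12, and adjusted p = 0.0840 with an estimated correlation). Of the 10 measured Hox genes of paralog groups 1 to 5, 2 rose, Hoxb4 (0.74) among them, or 6 adjusted over the list alone, and Hoxd1 (0.85) and Hoxd4 (0.79) did not pass over all features (camera adjusted p = 9.55e-08, and adjusted p = 0.127 with an estimated correlation). None of the 16 measured members of paralog groups 6 to 13 passed, with Hoxa7 at 0.58, and with the batch as a block Hoxa7 and Hoxd1 passed (adjusted p = 0.0496 and 0.0119).

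In the primitive streak and mesoderm list 6 of 20 members fell and 0 rose, or 8 falls adjusted over the list alone, Fgf8 (-1.22) and Evx1 (-0.69) among them (camera adjusted p = 1.18e-06, and adjusted p = 0.0840 with an estimated correlation). The primed epiblast list had 2 of 10 lower, or 4 adjusted over the list alone: Otx2 and the DNA methyltransferase Dnmt3b (-1.32), at adjusted p = 1.44e-05, and adjusted p = 0.337 with an estimated correlation. Of 38 neural progenitor genes 4 rose, or 5 adjusted over the list alone, the fourth being Nr2f1 (0.97), at adjusted p = 0.00591, and adjusted p = 0.424 with an estimated correlation. Meis1, Meis2 and Nr2f1 also stand in the retinoid list. Plat and Afp (1.52), the fetal serum protein of yolk sac and liver, rose in the endoderm list of 25, which had 5 rises and 1 fall adjusted over the list alone (adjusted p = 0.00127, and adjusted p = 0.337 with an estimated correlation). The Notch list ranked low with 1 of 16 lower, Dll3 (-1.10), and 1 higher, Dll4 (0.52), or 3 and 1 adjusted over the list alone, at adjusted p = 0.0269, and adjusted p = 0.285 with an estimated correlation. The fibroblast and matrix, stress and blood lists ranked high with 0 members past the test over all features (adjusted p = 0.0112, 0.0322 and 0.0391, against adjusted p = 0.619, 0.631 and 0.641 with an estimated correlation). Adjusted over the list alone, 5, 0 and 0 of their members passed. Postn stood at 2.56 and did not pass, and neither did any of the 26 pluripotency genes over all features (1 fall adjusted over the list alone), with Tdgf1 at -1.25 (list adjusted p = 0.488). With the batch as a block Postn and Tdgf1 passed (adjusted p = 0.0283 and 0.00985). The block gave 6 rises in the fibroblast and matrix list, 1 fall each in the blood and pluripotency lists, 4 falls in the primed epiblast list, 4 rises and 1 fall in the endoderm list, and 1 rise and 2 falls in the Notch list. The cell division list (adjusted p = 0.944) had a median of 0.00 and differed in sign between mean and test.

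In this comparison 177 features changed (limma), 98 higher and 79 lower, 78 of them at least 2-fold. Changes over all features correlated at 0.663 between batches. The count was 736 with the batch as a block, 98 with median centring in place of loess, and 19 when only the 4 arrays of both groups were fitted. It was 96 and 105 without the first and the second RA1 array and 86 without the second EB4 array. Without background correction it was 130, split into 56 higher and 74 lower. Of the 177 features 87 were also called on the sample channel alone. Otx2 (-2.69) and Dnmt3b (-2.28) were over 1.5-fold further from 0 on the sample channel alone, while Cltrn (1.51), Plat (1.78) and Usp18 (-1.75) were smaller than in the ratios, and Dll4 and Hoxb4 lost their calls (adjusted p = 0.437 and 0.133). Of 32 named changes 11 ended without 1 array and 21 under at least 1 other setting. Id2, Wnt2 and Dll4 did so without the first RA1 array (adjusted p = 0.175, 0.0534 and 0.184), and Bmper and Afp without the second (adjusted p = 0.147 and 0.0745). Vldlr did so without the first EB4 array (adjusted p = 0.159), and Otx2, Usp18 and Hoxb4 without the second (adjusted p = 0.0577, 0.0620 and 0.0522). The call of Meis2 ended when only both groups were fitted (adjusted p = 0.0863), and that of Wnt3 with the scanner's own ratios (adjusted p = 0.851).

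At RA2 the imprinted growth regulator Dlk1 (4.29 ± 0.52, 19.5-fold), Stra8 (3.71), Meis1 (3.61) and Meis2 (3.61) rose over EB4. Stra8 stood above Dlk1 on the sample channel alone, at 6.81 (112-fold) against 4.48. The interferon-induced GTPase gene Gbp2b (-3.47 ± 0.38), the immunoproteasome subunit Psmb8 (-3.36 ± 0.17), the thyrotropin-releasing hormone gene Trh (-2.87) and Gsc (-2.40) fell, with Trh at -3.92 and Gsc at -3.40 on the sample channel alone, both past Psmb8 at -3.33. Counted over all features, 9 of 23 retinoid genes and 5 of 10 Hox genes of groups 1 to 5 were higher, the latter 8 with the batch as a block, and 5 of 10 primed epiblast genes lower. At RA3 Dlk1 (4.27), Meis1 (3.75), the orphan nuclear receptor Nr2f1 (3.72 ± 0.17) and Stra8 (3.70) rose, of which Stra8 stood highest on the sample channel alone (7.61, 195-fold, against 4.43 for Dlk1). Psmb8 (-3.63), Trh (-3.11), Otx2 (-2.99) and the lymphotoxin gene Ltb (-2.78) fell, and Trh (-4.22) and Otx2 (-3.88) stood past Psmb8 (-3.43) on the sample channel alone. Of 22 cell division genes 11 were lower against 2 at RA2, or 12 against 4 with the batch as a block, a difference in counts that was not itself tested. In total 742 features changed at RA2 (363 higher, 379 lower) and 1659 at RA3 (765 higher, 894 lower), and changes over all features correlated at 0.780 and 0.794 between batches. With the batch as a block the counts were 2102 and 3361. On the sample channel alone they split differently, 337 higher and 195 lower at RA2 and 706 and 377 at RA3. Median centring gave 369 and 914, and fits of only both groups gave 149 and 300. The RA2 count was 258, 292 and 365 without the first RA2, the second EB4 and the second RA2 array. The RA3 count was 1011, 855, 735 and 1060 without the first EB4, first RA3, second EB4 and second RA3 array.

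The comparison of RA4 with EB4 spans the whole retinoic acid phase. Nr2f1 rose 14.5-fold (3.86 ± 0.17, adjusted p = 5.62e-06), Meis1 13.7-fold (3.77 ± 0.18) and Nr2f2 9.81-fold (3.29 ± 0.24). The yolk sac and liver gene Afp rose 18.0-fold (4.17 ± 0.21), and the cardiac transcription factor Mef2c 7.15-fold (2.84 ± 0.53). Dlk1 rose 20.6-fold (4.37 ± 0.52). Otx2 (-3.22 ± 0.24), the Nodal coreceptor Tdgf1 (-2.90 ± 0.27) and Dnmt3b (-2.85 ± 0.10) fell. On the sample channel alone Stra8 stood at 7.72, above Dlk1 at 4.45, and Tdgf1 at -5.55, Dnmt3b at -4.09 and Otx2 at -4.01, while other changes were smaller than in the ratios, such as those of Foxa1 (2.09 in the ratios and 1.59) and Hes5 (2.35 and 1.96).

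The insulin-like growth factor binding protein Igfbp5 (4.11), the platelet receptor gene Clec1b (3.88), Stra8 (3.77), Meis2 (3.73), Plat (3.04) and Cebpd (2.83) rose as well. Psmb8 fell 14.2-fold (-3.83 ± 0.17), and Trh (-3.25), Ltb (-2.96), carbonic anhydrase Car2 (-2.75), Gsc (-2.71), Chst7 (-2.56), the neuronal gene Stmn2 (-2.24) and the Wnt target Sp5 (-2.15) fell with it. Psmb8 stood at -3.51 on the sample channel alone, short of Trh (-4.29) and Car2 (-3.76). Tdgf1 had a second probe, at -1.72. Of 23 retinoid genes 10 rose and 0 fell, or 14 and 1 adjusted over the list alone (camera adjusted p = 3.07e-09, and adjusted p = 0.127 with an estimated correlation). Of the 10 Hox genes of groups 1 to 5, 6 rose, on either adjustment, Hoxd4 (2.66), Hoxa2 (2.07) and Hoxc4 (1.77) among them (adjusted p = 1.57e-06, and adjusted p = 0.148 with an estimated correlation). In groups 6 to 13 1 of 16 rose, Hoxa7 (1.37), on either adjustment, or 3 with the batch as a block, and that list did not pass (adjusted p = 0.168).

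Neural progenitor genes ranked high, with 9 of 38 higher and Cdh2 (-0.90) lower, or 10 and 1 adjusted over the list alone. Hes5 (2.35), a Notch target of neural stem cells, and Lhx2 (2.32) were among the risers, and Pax6 (0.50) and Sox1 (0.02) did not pass (list adjusted p = 4.04e-05, and adjusted p = 0.337 with an estimated correlation). Of 38 neuronal genes 6 rose and 2 fell, or 7 and 3 adjusted over the list alone, with the adhesion gene Cntn2 at 1.34 and Stmn2 and Elavl2 (-0.32) lower, while Tubb3 (0.82) and Nefm (1.51) did not pass (list adjusted p = 0.0192, and adjusted p = 0.631 with an estimated correlation). The heart and muscle list had 5 of 14 higher, Tnnt2 (2.50) and Myl4 (2.44) among them, and 1 lower, or 6 and 1 adjusted over the list alone (adjusted p = 0.0369, and adjusted p = 0.619 with an estimated correlation). Without the second RA4 array the neuronal and heart lists no longer passed, with medians of 0.107 and 0.287 against 0.092 and 0.316 with it. The endoderm list had 5 of 25 higher, Foxa1 (2.09) among them, and Sox17 (-1.44) and Tfpi (-0.44) lower, or 7 and 2 adjusted over the list alone (adjusted p = 0.0112, and adjusted p = 0.388 with an estimated correlation). In the blood and endothelium list Cd34 (1.72) and Tie1 (0.58) rose, the same 2 of 16 adjusted over the list alone (adjusted p = 0.0255, and adjusted p = 0.631 with an estimated correlation). With the batch as a block Nefm passed (adjusted p = 0.0126), and 11 neuronal genes rose and 3 fell, 9 endoderm genes rose and 3 fell, and 6 blood and endothelium genes rose and 1 fell.

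Of the cell division genes 15 of 22 fell and 0 rose, or 17 adjusted over the list alone, by modest amounts such as Ccnb2 at -0.70, Ccna2 at -0.67 and Mcm6 at -0.66 (adjusted p = 1.38e-09, and adjusted p = 0.180 with an estimated correlation). The cell cycle inhibitors Cdkn1c (1.07), Cdkn2b (0.87) and Cdkn2d (0.39) rose among 11 measured, on either adjustment, and their list did not pass (adjusted p = 0.207). Hypoxia and glycolysis genes fell in 10 of 19 cases with 0 higher, or 12 adjusted over the list alone, the glucose transporter Slc2a1 (-1.49), Eno1 (-1.30) and Ldha (-1.28) among them (adjusted p = 1.48e-07, and adjusted p = 0.404 with an estimated correlation). The primed epiblast list had 5 of 10 lower, or 7 adjusted over the list alone (adjusted p = 5.18e-05, and adjusted p = 0.337 with an estimated correlation). The pluripotency list had 6 of 26 lower, Tdh (-1.98) and Pou5f1 (-0.96) among them, and 1 higher, Klf4 (0.43), or 11 and 1 adjusted over the list alone, and 16 and 1 with the batch as a block (without the block adjusted p = 0.000332, and adjusted p = 0.447 with an estimated correlation). In the primitive streak list 7 of 20 fell and 3 rose, or 7 and 4 adjusted over the list alone, T (-1.70) down and Foxc1 (1.91) up, without passing (adjusted p = 0.0572). Without the second RA4 array that list passed (adjusted p = 0.0379, and adjusted p = 0.383 with an estimated correlation). Notch genes went both ways, 6 of 16 higher and 2 lower on either adjustment, with Dll4 at 1.48 and Dll3 at -0.67; the median was -0.08, the mean 0.29 and the test did not pass (adjusted p = 0.220). Glial and adult brain genes did not stand apart (adjusted p = 0.965 and 0.582), with Olig1 (0.53) up and Gja1 (-1.04) down among 12 glial genes and Gad1 (-0.58) down among 28 brain genes. The glial median was -0.02 and the mean 0.01. The neural crest (adjusted p = 0.732), germ cell (adjusted p = 0.944) and trophoblast (adjusted p = 0.667) lists also had medians and means of opposite sign, with Twist1 (2.20) up and Msx2 (-1.30) down in the first. The fibroblast and matrix list held rises of Fstl1 (1.04) and Postn (2.33), and the stress list a rise of Herpud1 (1.25) and 3 falls, without passing (adjusted p = 0.252 and 0.938). With the batch as a block these lists had 3 rises and 1 fall and 3 rises and 6 falls, the neural crest list 3 and 3 and the brain list 2 and 2. Postn lost its call without the second RA4 array (adjusted p = 0.230).

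**Figure D2:**
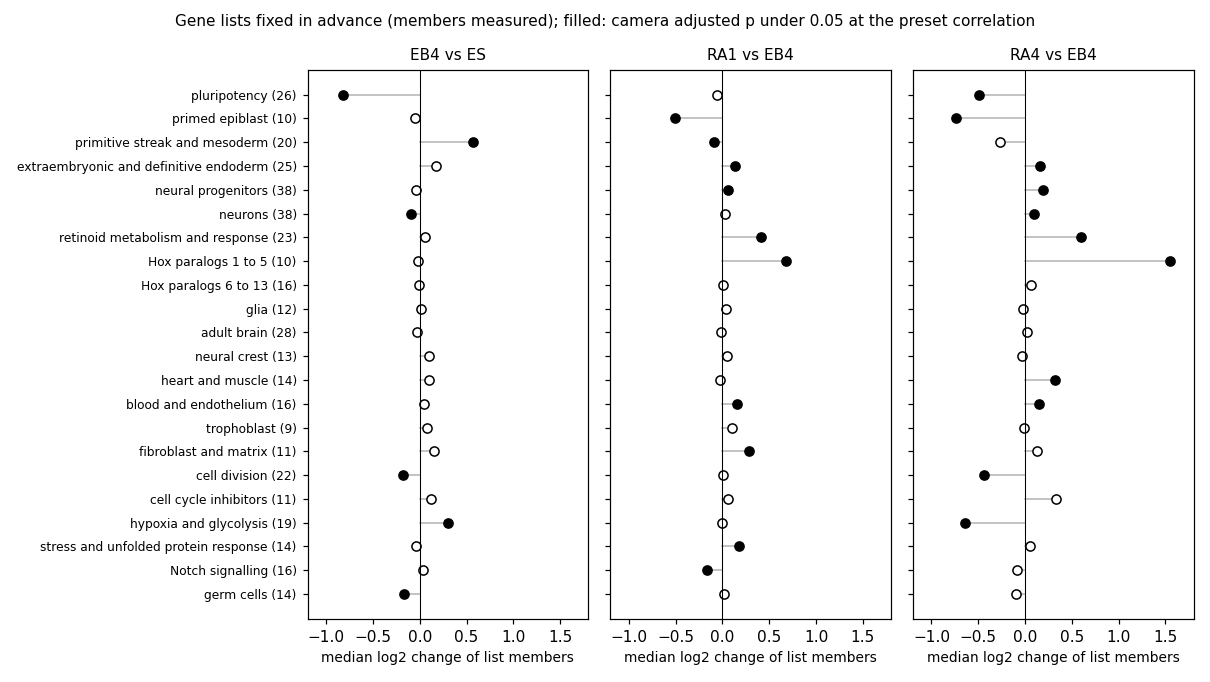
Median log2 change of the measured members of each of the 22 gene lists (horizontal axis; members measured in brackets) in EB4 against ES, RA1 against EB4 and RA4 against EB4; filled points passed camera at the preset correlation and open points did not, and no list passed with an estimated correlation. Hox genes of paralog groups 1 to 5 moved from a median of 0.68 at RA1 to 1.55 at RA4, and cell division genes stood at -0.44 at RA4.

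In RA4 against EB4, 2811 features changed (limma), 1333 higher and 1478 lower, of which 447 changed at least 2-fold. The changes correlated at 0.840 between batches over all features. The source name of the second RA4 array reads as a brain control, while its title and description give the 4-day group, so counts are also given without it: 1400, or 704 higher and 696 lower. The count was 1401 without the first RA4 array, 1642 without the second EB4 array, 4846 with the batch as a block and 1822 with median centring, and it split into 1231 higher and 730 lower on the sample channel alone. Of the 2811 features 1308 were also called on the sample channel alone. Gsc (-3.46), Myl4 (3.27) and Cdkn1c (2.13) were over 1.5-fold further from 0 on the sample channel alone, where the calls of Hes5, Mcm6, Olig1 and Postn ended (adjusted p = 0.134, 0.0634, 0.0781 and 0.0535). Of 68 named changes 15 ended without 1 array and 14 under at least 1 other setting. Mef2c and Olig1 did so without the first RA4 array (adjusted p = 0.0537 and 0.153), Hes5 and Cdkn2d without the second (adjusted p = 0.283 and 0.191), and Tnnt2 and Cdkn1c without the second EB4 array (adjusted p = 0.0696 and 0.212).

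Set against undifferentiated ES cells, RA4 differed in 5946 features, 2801 higher and 3145 lower, and 1417 changed at least 2-fold. Without the second RA4 array the count was 4251. Afp was not well above background in ES cells and its sample signal after loess and Aquantile was at least 32.4-fold higher at RA4 against the lowest signal above background, and 35.3-fold as measured, both open to dye bias (adjusted p = 2.06e-06 in the ratios). The bound holds on that scale only, since the ratios gave 32.35-fold and the sample channel alone, quantile-normalized, 31.5-fold. Meis2 (4.91 ± 0.27), Asb4 (4.80 ± 0.15) and Igfbp5 (4.52 ± 0.31) rose too, and Asb4 stood highest of these on the sample channel alone (6.24, 75.7-fold, against 5.16 for Meis2). The Nodal antagonist Lefty1 (-3.67 ± 0.54), Nr0b1 (-3.59 ± 0.42) and the germ cell gene Morc1 (-3.53 ± 0.26) were among the largest falls, with Lefty1 at -4.31 and Morc1 at -3.91 past Nr0b1 at -3.27 on the sample channel alone. Changes over all features correlated at 0.930 between batches.

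Few features passed the test between successive days, and changes over all features correlated between the batches at 0.540 from RA1 to RA2, 0.415 from RA2 to RA3 and 0.0635 from RA3 to RA4. From RA1 to RA2 13 features changed (8 higher, 5 lower). Igfbp5 (2.54), the atrial myosin light chain Myl4 (2.53), Nr2f1 (2.02) and Afp (1.76) rose, and Psmb8 (-2.18), Trh (-1.62), Cltrn (-1.15) and Defa31 (-0.58) fell. The count was 183 with the batch as a block, and 10 with median centring, 5 higher and 5 lower. It was 3 without the first RA2 array, 6 and 8 without the first and second RA1 array, 8 without either ES array, and 21 without any 1 of the EB4 or RA3 arrays. Without the first RA2 array the calls of Afp, Igfbp5, Cltrn, Trh and Defa31 ended (adjusted p = 0.138, 0.247, 0.0837, 0.0837 and 0.251), and without the first RA1 array that of Myl4 (adjusted p = 0.0841). On the scanner's own ratios the count was 5, on the deposited values also 5, without background correction 4 and with only both groups fitted 0. At an unadjusted p under 0.05 stood 876 of 20257 features from RA2 to RA3 and 510 from RA3 to RA4. Both are smaller shares than the 0.05 that unchanged features would give. From RA2 to RA3 limma called 0 features after adjustment, and 41 with the batch as a block. Without either RA4 array it called 3, without the second RA3 array 1, and on the scanner's own ratios 1, and on the deposited values 2. From RA3 to RA4 it called 2, Gdf10 (1.08 ± 0.11) and Cldn11 (0.69 ± 0.06), against 510 at an unadjusted p under 0.05 and 22 with the block, and 0 without the second RA4 array. With each of the 12 arrays left out in turn, Gdf10 lost its call in 11 fits and Cldn11 in 10, so neither call was stable. A moderated F test over all 6 groups found 4840 of 20257 features (23.9%) to vary. The count was 3973 without the second RA4 array and 3221 without the second ES array.

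**Figure D3:**
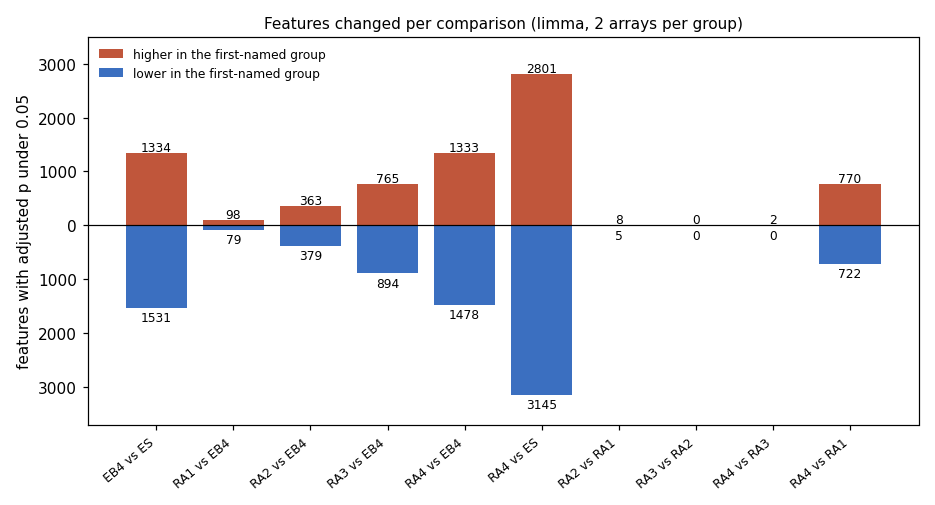
Number of features with an adjusted p under 0.05 (vertical axis) in each of the 10 comparisons (horizontal axis), counted upward when higher and downward when lower in the first-named group. RA4 against ES gave 5946 and the step from RA2 to RA3 gave 0.

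The difference between RA4 and RA1 was tested directly, since both share the EB4 start. Later rises were those of Clec1b (3.33 ± 0.23), Igfbp5 (3.11 ± 0.31), Cebpd (2.96 ± 0.24) and Myl4 (2.95 ± 0.24), and Nr2f1 (2.89) and Nr2f2 (2.25) were higher too. Nr2f2 had stood at 1.04 at RA1 without passing (adjusted p = 0.107, and 0.000525 with the batch as a block). Lefty1 (-3.11 ± 0.54), Psmb8 (-2.64 ± 0.17), Car2 (-2.37 ± 0.16) and Tdo2 (-2.07 ± 0.39) fell. Myl4 (3.67) and Lefty1 (-3.79) were over 1.5-fold further from 0 on the sample channel alone, and Car2 (-2.85) stood past Psmb8 (-2.33). Cell division genes were lower in 11 of 22 cases, or 18 adjusted over the list alone (camera adjusted p = 2.58e-12, and adjusted p = 0.133 with an estimated correlation). Hypoxia and glycolysis genes were lower in 9 of 19 cases, or 13 with 1 higher adjusted over the list alone (adjusted p = 2.19e-08, and adjusted p = 0.386 with an estimated correlation). Notch genes were higher in 5 of 16 cases, Mfng (1.07) and Hey1 (0.98) among them, or 8 adjusted over the list alone, and 8 with 1 lower with the batch as a block (without the block adjusted p = 0.000106, and adjusted p = 0.0840 with an estimated correlation). Hox genes of groups 1 to 5 were higher in 5 of 10 cases, Hoxd4 (1.88) and Hoxa2 (1.39) among them, or 5 higher and 1 lower adjusted over the list alone (adjusted p = 0.00591, and adjusted p = 0.386 with an estimated correlation). The neural progenitor list ranked high with 3 of 38 higher, Lhx2 (1.70) among them, on either adjustment, or 8 and 3 lower with the batch as a block, and did not pass without the second RA4 array (without the block adjusted p = 0.00144, 0.0551 without that array, and adjusted p = 0.408 with an estimated correlation).

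In the heart and muscle list Myl4, Myh6 (1.56) and Tnni1 (0.69) rose and Myl3 (-0.49) fell among 14, or 7 and 1 adjusted over the list alone (adjusted p = 0.00394, and adjusted p = 0.424 with an estimated correlation). Pluripotency genes ranked low with Tdgf1 (-1.65), Tdh (-1.44), Lefty1 and Utf1 (-0.57) lower and Klf4 (0.59) higher among 26, or 7 and 1 adjusted over the list alone (adjusted p = 7.75e-05, and adjusted p = 0.424 with an estimated correlation). Otx2 (-1.41) and Dnmt3b (-1.54) fell further among 10 primed epiblast genes, with 4 falls adjusted over the list alone (adjusted p = 0.00545, and adjusted p = 0.424 with an estimated correlation). Of 23 retinoid genes 5 rose, Foxa1 (1.10) among them, and Cyp26a1 (-0.77) fell, or 8 and 1 adjusted over the list alone (adjusted p = 0.00162, and adjusted p = 0.386 with an estimated correlation). Neuronal genes ranked high with Cntn2 (1.19) up and Stmn2 (-1.71) down among 38, or 4 and 1 adjusted over the list alone (adjusted p = 0.0322, and adjusted p = 0.641 with an estimated correlation). With the batch as a block the heart and muscle list had 7 rises and 1 fall, the pluripotency list 14 falls and 1 rise, the primed epiblast list 4 falls, the retinoid list 8 rises and 2 falls and the neuronal list 7 rises and 2 falls. Without the second RA4 array the neuronal list did not pass (adjusted p = 0.267) and Myh6 and Foxa1 lost their calls (adjusted p = 0.145 and 0.132). Without the first RA4 array Tdgf1, Tdh, Otx2, Cntn2 and Stmn2 lost theirs (adjusted p = 0.0619, 0.114, 0.0720, 0.0786 and 0.102). On the sample channel alone the calls of Foxa1, Hey1, Otx2 and Stmn2 ended (adjusted p = 0.188, 0.0579, 0.0557 and 0.0548), as did that of Otx2 without background correction (adjusted p = 0.256) and that of Tdgf1 on the scanner's own ratios (adjusted p = 0.313).

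Between RA4 and RA1 1492 features changed, 770 higher and 722 lower, and 527 without the second RA4 array. Changes over all features correlated at 0.777 between batches. The count was 445, 700 and 858 without the first RA4, first RA1 and second RA1 array, 3570 with the batch as a block, 861 with median centring and 777 with only both groups fitted. The sample channel alone gave 585 higher and 278 lower. Of 53 named changes 25 ended under at least 1 other setting and 25 without 1 array, Hoxd4 without the second RA4, Lefty1 without the first RA4 and Tdo2 without the first RA1 array among them (adjusted p = 0.213, 0.0720 and 0.0877).

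Of the 177 features called at RA1, 155 (87.6%) were called the same way at RA4, 82 higher and 73 lower, and 1 the opposite way. The latter, named after its values were seen, was Sec14l2, at 0.74 at RA1 and -0.61 at RA4. Independent lists of these sizes would share 12.2. Unchanged groups simulated against the same EB4 arrays shared 0.02 on average and at most 1. As no simulated group changed, few features could be called, so that count cannot show how far shared controls raise an overlap. The simulations held no batch difference and were not repeated with the block. The covariance of the changes was 0.0468 against 0.00786 simulated, a difference of 0.0389, and the correlations were 0.624 and 0.499. Part of the excess may come from sharing the controls. With the EB4 arrays split, 1 for each comparison, and the lone array assumed to vary like the other groups, the overlap was 73 of 86 features called at RA1 one way and 109 of 140 the other way, with 3.99 and 5.77 for independent lists. The covariances were then 0.0354 and 0.0357. With the batch as a block, which takes out the batch difference that a split brings in, the overlap was 205 of 266 and 308 of 432, with 22.2 and 33.9 for independent lists and covariances of 0.0395 and 0.0419. The overlap was 102 without the second RA4 array, 80, 87 and 77 without the first RA1, second RA1 and second EB4 array, 585 with the batch as a block, 87 with median centring and 18 with only both groups fitted.

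The second RA4 array was set against its partner because of its conflicting labels. The RA4 arrays correlated at 0.967 over all features, within the 0.935 to 0.975 of the other pairs. The 28 adult brain genes had a median difference of 0.00 between them, and 1 of the 28, the somatostatin gene Sst, was over 2-fold higher on the second (0.45 and 1.52). The myelin genes Mbp (-0.09 and -0.09) and Mobp (-0.07 and -0.19) and the synaptic gene Snap25 (-0.12 and 0.12) were near the reference level on both arrays. The second RA4 array correlated at 0.969 with the second RA3 array.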

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

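Chosen only after the result was seen were the test of the interferon-linked genes within each batch, the test of exchanged 3-day and 4-day arrays, both tests of the reference channel and the scaling of its brightness, while the leukocyte and adult brain tests were written down first.

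The differences below stand out because the change from EB4 differed between RA1 and RA4 by a direct test of RA4 against RA1. Of the 22 gene lists 10 did so by camera at the preset correlation, and 0 of them with an estimated correlation (adjusted p of 0.0840 or more). Medians of RA4 minus RA1 were 0.467 for Hox groups 1 to 5, 0.510 for heart and muscle, 0.320 for Notch signalling, 0.192 for retinoid metabolism and response, 0.166 for neural progenitors and 0.126 for neurons. They were -0.617 for pluripotency, -0.217 for primed epiblast, -0.445 for cell division and -0.686 for hypoxia and glycolysis.

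Of 41 genes named at RA1 or RA4, 18 differed between these times, against 1492 of 20257 features over the array. The 41 were named for large changes on these same arrays, so a larger share among them may follow from that choice. Higher at RA4 than at RA1 were Afp (2.65), Igfbp5 (3.11), Nr2f1 (2.89), Plat (1.15), Clec1b (3.33), Cebpd (2.96) and Nr2f2 (2.25), of which Clec1b and Cebpd stood at 0.55 and -0.13 at RA1. Lower at RA4 than at RA1 were Dnmt3b (-1.54), Gsc (-0.636), Otx2 (-1.41), Psmb8 (-2.64), Trh (-2.01), Tdgf1 (-1.65), Ltb (-1.85), Car2 (-2.37) and Stmn2 (-1.71). The call of Gsc ended without the second RA4, first RA1 and first RA4 array (adjusted p = 0.0921, 0.0669 and 0.0620), without background correction (-0.17, adjusted p = 0.467), on the sample channel alone (adjusted p = 0.0866) and with only both groups fitted (adjusted p = 0.0574). Those of Otx2, Tdgf1 and Stmn2 ended without the first RA4 array (adjusted p = 0.0720, 0.0619 and 0.102). Bmper went from -1.58 at RA1 to -0.12 at RA4 (difference 1.46), and Cltrn from 1.68 to 0.07 (difference -1.61).

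In a list of 29 interferon-linked genes written after some of its genes had been seen, 13 members, Usp18 (3.30), H2-T22 (2.22) and Psmb8 (2.08) among them, rose from ES to EB4 and 14 fell from EB4 to RA4. Both changes share the same 2 EB4 arrays, whose own deviation would give a rise followed by a fall. The fall is therefore not separate evidence for the rise. Leukocytes in the EB4 samples would bring their own transcripts, but 25 leukocyte genes had a mean change of 0.0571 against 0.745 for the interferon list, with Ptprc at 0.25 and Cd74 at 0.13, neither past the test. The mean change of the 29 genes was 0.574 in the lower batch and 0.917 in the other, so the rise of this list was not confined to a single batch. Gbp2b, Irgm1, Psmb8 and Usp18 had been named by a rule that asked both arrays of a group to lie beyond both of the other. Batch means without them were not taken, so presence in both batches was partly a condition of entry. A response of the aggregated cells themselves stays a hypothesis, and with an estimated correlation the list did not pass (adjusted p = 0.175).

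The second 4-day array carries conflicting labels. Brain RNA on it is argued against by a median difference of 0.00366 for 28 adult brain genes between the second and the first 4-day array. An exchange of the second 3-day and second 4-day arrays would turn the sign of the 4-day minus 3-day differences in that batch. Those differences correlated at 0.0635 between batches, near 0, so an exchange could not be told from a step too small to measure.

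The reference channel moved with the sample channel for some genes, although the same pooled RNA was used throughout: for Stra8 the reference brightness went from 75.3 in EB4 to 1234 in RA4 and for Tdgf1 from 527 to 20.3, but for Meis1 (2294 to 1909), Nr2f1 (1737 to 1219) and Dlk1 (4680 to 3170) it fell while the sample signal rose, and for Asb4 it was 269 and 281. With the reference of each array scaled to a common median these last 4 went from 1932 to 2348, 1454 to 1503, 3846 to 3904 and 230 to 345. Normalization of the ratios is argued against, since in brightness before normalization the slope of the reference change on the sample change was 0.218 (SE 0.0145) over 236 features, 84.7% of them in the same direction. The 236 were chosen for a sample change over 1.5 on the log2 scale, relative to the median change. A fixed share of the sample dye read in the reference channel would give a like share for every gene. That share was measured over 13 features with a sample brightness change over 5000 and a reference brightness under 500 in the group with the dimmer reference. The 90th percentile of the share was 4.99 times the 10th, or 3.89 times after the scaling. Both values lie beyond the bound of 3 set for excluding this explanation, but their 95% bootstrap intervals, 2.38 to 37.7 and 2.58 to 6.26, include it; the intervals were added after the first value was seen, without them the explanation would have counted as excluded, and it is left open here, with no biological explanation tested.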

How the results depend on the processing

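Chosen only after the data had been seen were the sample channel alone, an estimated correlation together with the block or without the second RA4 array, and the split of the EB4 arrays. Of 253 named changes 150 kept their direction and call under all 22 settings, 103 lost the call under at least 1, and 1 reversed: Stra8 in EB4 against ES, 1.37 on the deposited table. Aquantile leaves ratios unchanged by construction, and no filter on dim probes and the use of all probes moved no count by over 1.5 times. No setting shifted the median of all features by over 0.1. At least 96.0% of sample signals per array stood well above background, and the number of arrays, 2 per group, limits the precision. On the sample channel alone 177 of 253 named changes were larger than in the ratios (median ratio 1.06). Except where fewer arrays in the fit or a lower spread after the block shows it by construction, the cause was not tested.

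With the replicate block, which takes the difference between batches out of the spread, counts rose to 4577 (EB4 against ES), 736 (RA1 against EB4), 2102 (RA2), 3361 (RA3), 4846 (RA4), 183 (RA2 against RA1), 41 (RA3 against RA2), 22 (RA4 against RA3) and 3570 (RA4 against RA1), and the overlap of RA1 and RA4 calls to 585. The block changed the call of 1 of 88 list tests, endoderm in EB4 against ES, and of 0 of the 253 named changes. The glial list in RA4 against EB4 turned direction without passing (median -0.022) with the block, alone and with an estimated correlation. Fits of only both groups compared, with fewer arrays to estimate the spread, gave 19 (RA1 against EB4), 149 (RA2), 300 (RA3), 777 (RA4 against RA1), 0 (RA2 against RA1) and 0 (RA4 against RA3), and an overlap of 18 (limma). With 1 EB4 array for each comparison the overlap was 73 and 109 without the block and 205 and 308 with it. The main counts at an unadjusted p under 0.05 were 1427 of 20257 for RA2 against RA1 and 510 for RA4 against RA3. The latter is a smaller share than the 0.05 that unchanged features would give.

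Median centring gave 98, 369, 914 and 1822 for RA1 to RA4 against EB4, 861 for RA4 against RA1, 0 for RA4 against RA3 and an overlap of 87. Without background correction RA2 against RA1 gave 4 and RA4 against RA3 gave 1. The scanner's own ratios gave 5 for RA2 against RA1, 1 for RA3 against RA2 and 0 for RA4 against RA3, and a correlation of 0.945 between the RA4 arrays. On these ratios 4 lists that had not passed turned direction: neural progenitors in EB4 against ES (median -0.0335), glia (-0.00535) and germ cells (-0.0953) in RA4 against EB4, and trophoblast in RA4 against RA1 (-0.0140). The deposited table gave 4770 for EB4 against ES, 5 for RA2 against RA1 and 2 for RA3 against RA2. The sample channel alone gave 1861 for EB4 against ES, 1083 for RA3 against EB4, 863 for RA4 against RA1 and 0 for RA4 against RA3. Of the main calls it kept 1545 of 2865 in EB4 against ES and 87 of 177 in RA1 against EB4. It kept 1308 of 2811 in RA4 against EB4 and 536 of 1492 in RA4 against RA1. Of the 37 list calls at the preset correlation 0 passed with an estimated one, 0 with the replicate block and an estimated one, and 0 with an estimated one when the second RA4 array was left out.

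With each array left out in turn, counts ranged from 1604 to 2955 for EB4 against ES, lowest without the second ES array, and from 86 to 199, 258 to 772, 735 to 1707 and 1400 to 2879 for RA1, RA2, RA3 and RA4 against EB4. These were lowest without the second EB4, first RA2, second EB4 and second RA4 array. They ranged from 4251 to 5984 for RA4 against ES, from 445 to 1541 for RA4 against RA1, from 3 to 21 for RA2 against RA1, from 0 to 3 for RA3 against RA2 and from 0 to 2 for RA4 against RA3. The features varying over the 6 groups ranged from 3221 to 4931 and the overlap from 77 to 175. Without the second RA4 array 34 list tests passed, and the fibroblast and matrix list in RA4 against RA1, which had not passed, turned direction (median 0.0621).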

Other observations

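The interferon, imprinted, sterol, Nodal and leukocyte lists below were written only after the data had been seen, as was the batch test at the end, and p-values are from fits without the batch as a block. Changes to EB4 and from EB4 share the same 2 EB4 arrays, so a rise followed by a fall is not 2 separate results.

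Of 29 genes of the interferon response and antigen processing, 13 rose, 0 fell and 16 did not pass from ES to EB4, or 20 rose and 1 fell with the batch as a block, Isg15 (1.64), Irgm1 (1.32) and the proteasome activator Psme2 (1.10) among them (camera adjusted p = 3.93e-12, and adjusted p = 0.175 with an estimated correlation). From EB4 6 fell at RA1, or 13 with the block, 14 at RA2 and 14 at RA4, and the other members did not pass, with the immunoproteasome subunits Psmb8 at -3.83, Psmb10 at -2.04 and Psmb9 at -1.42 at RA4 (adjusted p = 4.73e-18, 1.03e-21 and 2.50e-10, each against adjusted p = 0.175 with an estimated correlation). Between RA1 and RA4 6 fell, or 10 with 2 rises with the block (adjusted p = 0.0178, and adjusted p = 0.5002 with an estimated correlation). The rule for named genes had taken Gbp2b, Irgm1, Psmb8 and Usp18. Without them the 25 other members had camera adjusted p = 7.58e-09 in EB4 against ES and 2.70e-12, 4.56e-15 and 1.65e-07 at RA1, RA2 and RA4 (each adjusted p = 0.225 with an estimated correlation). Between RA1 and RA4 they had adjusted p = 0.0347 (adjusted p = 0.665 with an estimated correlation). The whole list was written after the data were seen, so leaving these genes out does not make the test independent of these arrays.

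Among 23 imprinted genes Asb4, Peg3 (1.35) and Igf2r (0.94) rose from ES to EB4 (adjusted p = 0.00917), and 9 rose and 3 fell from EB4 to RA4 (adjusted p = 0.00748), both with adjusted p = 0.175 with an estimated correlation. Dlk1 (4.37) and Igf2r (1.23) were among the rises, and Phlda2 (-1.58) and Snrpn (-1.48) among the falls. At RA2 4 rose and 1 fell, or 8 and 5 with the block (adjusted p = 0.00327, and adjusted p = 0.175 with an estimated correlation), and the list did not pass at RA1 (adjusted p = 0.119). From RA1 to RA4 it ranked high with 2 higher and 1 lower, or 7 and 4 with the block (adjusted p = 0.0280, and adjusted p = 0.225 with an estimated correlation). Without Asb4 and Dlk1, which the rule for named genes had taken, it did not pass from ES to EB4 (adjusted p = 0.0507), at RA1 (0.167), at RA4 (0.0507) or between RA1 and RA4 (0.180), and passed at RA2 alone (adjusted p = 0.0324, and adjusted p = 0.225 with an estimated correlation). Of 13 sterol synthesis genes Sc5d (0.82) rose in EB4, or 5 with the block (adjusted p = 0.00145, and adjusted p = 0.267 with an estimated correlation). At RA4 5 fell from EB4, Fdps (-0.78), Pmvk (-0.62) and Mvd (-0.57) among them, or 7 with 1 rise with the block (adjusted p = 0.00917, and adjusted p = 0.358 with an estimated correlation). From RA1 to RA4 4 fell, or 9 with the block (adjusted p = 0.000292, and adjusted p = 0.236 with an estimated correlation), and RA1 and RA2 did not pass (adjusted p = 0.193 and 0.585). The 14 Nodal genes, 6 of which stand in other lists, did not pass camera in any of the 5 comparisons (lowest adjusted p = 0.113), but passed fry, which does not compare a list with other genes, in all 5 (highest adjusted p = 0.0390). From ES to EB4 3 of them rose and 2 fell, or 4 and 4 with the block, and from EB4 to RA4 1 rose and 3 fell, or 2 and 5 with the block. The 25 leukocyte genes passed neither camera nor fry (lowest adjusted p = 0.214).

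A common deviation of arrays in the same batch was also tested. The batch difference correlated with the change from EB4 to RA4 at -0.0157 in RA1, 0.0534 in RA2 and -0.0305 in RA3. It also correlated with the mean batch difference of the quantile-normalized reference channel in the other groups. These values were -0.185 in ES, -0.254 in EB4, and -0.348, -0.364, -0.286 and -0.326 in RA1 to RA4. No explanation was settled by these values.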
